A study of Mus musculus with 9 samples.

How the data were processed

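RNA was measured in keratinocytes of C57BL/6 mouse skin at postnatal days 1, 7 and 14, with 3 libraries per day and 9 in all. Per the labels' protocols, viable cells without the leukocyte surface marker CD45.2 were sorted from fresh skin, column-purified RNA was made into stranded mRNA libraries, and these were sequenced on a NovaSeq instrument. The gate excludes leukocytes and dead cells but selects no keratinocyte marker, so other CD45.2-negative skin cells can be among those sorted. The labels do not say whether the libraries of a day came from separate animals or pools, nor the sex of the animals. The p-values therefore measure only the spread between these libraries, which may be technical.

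Per the submitters' processing notes, reads were handled with bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 1.3.4d against the mouse build mm10. The counting step, its strand setting and the annotation release are not given in the sources used here. Per the file headers, the deposited table holds read counts per gene, which are whole numbers not normalised by the authors, for 24532 genes with NCBI gene identifiers. Among counts from 1 to 20, even values were commoner than odd ones in each of the 9 libraries (from 53.1% to 55.1% even). Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads of near-identical copies, such as the H2 class I, Skint, Sprr2, stefin A, hemoglobin and histone genes, may have been split between members, so values of single members of these families are uncertain. A further 18 columns of TPM and FPKM values, whose headers give the day but not the sample, were not used. Genes encoded by the mitochondrial genome were not analysed here.

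Columns were assigned to days by their headers. The headers of the libraries taken as day 1 read D0, a day that no sample title has. They were assigned to day 1 because days 7 and 14 have headers of their own. Headers number the libraries 4, 5 and 6 at days 1 and 14, and 1, 2 and 3 at day 7, where the header style also differs. These numbers name the libraries in the text. Titles number the samples of each day from 1 to 3, so headers cannot be matched to titles within a day.

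Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, 1 model over all 9 libraries with day as a factor). The filterByExpr filter left 14507 genes. P-values were adjusted with the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 with no fold minimum was called a change. The 3 pairs of days were compared, and 1 test asked for any difference over the 3 days. A turn at day 7 was a change in both steps with opposite signs. Levels are library-scaled counts (CPM) on the TMM-scaled libraries, as mean ± SD over 3 libraries, and log2 fold changes are given ± SE. Where all libraries of a day had 0 counts, a fold is given only as a lower bound against 3 counts per library (0.0472 CPM at day 1, 0.0514 at day 7 and 0.0587 at day 14, which cover counting error only). Coordinates are those of the mm10 assembly, matched by gene identifier for 24462 of the 24532 genes.

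Gene lists of 7 kinds (epidermis, hair follicle, growth, metabolism, immune, other cell types of skin, and quality) were tested with camera (limma 3.58.1, inter-gene correlation 0.01) and adjusted over the 40 lists with at least 3 tested members. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. The share of all counts that each list took in each library was compared between days with an exact permutation test over 1680 assignments of the 9 libraries, whose smallest possible p is 0.00357. No gene stands in more than 1 list. The tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. By that rule, the text names, for each pair of days, up to 6 genes with the largest rise and 6 with the largest fall among changed genes with named symbols, a mean of at least 10 CPM in the higher day and no overlap between libraries, with at most 2 per list or family. It adds up to 3 changed members of highest mean level from each list past the camera test and up to 4 changed members of smallest adjusted p from each immune list. Krt5, Krt14, Krt1, Krt10, Mki67, Ptprc, Col1a1, Xist and Ddx3y are always included. For the turn, it takes the 5 genes in each direction with the largest smaller step. Where fewer are given, they are taken in this order, except that some genes the rule names are not reported here.

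The same steps were tested on simulated counts drawn from the means and totals of these libraries over 14306 genes left by the filter. Of genes simulated with a change of 1.5-fold, 76% were recovered for day 7 versus day 1, 79% for day 14 versus day 7 and 84% for day 14 versus day 1. For a change of 1.25-fold the shares were 28%, 43% and 38%. False calls were 10 of 159, 12 of 322 and 12 of 164. These values come from 1 run with 50 or 100 changed genes per fold, drawn from genes with a mean of at least 1 CPM. Far more genes changed in the data, so the values do not give the recovery or the rate of false calls there. In 10 simulations of unchanged groups, with 14507 genes each, at most 3 genes were called for a pair of days. No list passed camera for day 7 versus day 1 in them. Genes were drawn independently of each other, so these simulations cannot show how often camera passes lists of correlated genes. With the 15 class I genes doubled at day 7 in a further simulation, that list passed camera and so did 1 other list, that of sex-linked genes, which was not changed. The alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a stricter threshold, a test against a fold of 1.5, fits on the compared days only, and fits without each library in turn. Fits on autosomal genes only, and with the header number as a block, were added after the data were seen. Not every alternative applies to each result, and ranges of adjusted p over the alternatives leave out the estimated correlation, fry, the fold of 1.5 and the stricter threshold, which ask another question.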

Results

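Gene expression was measured in keratinocytes, the main cell type of the epidermis, sorted from mouse skin at postnatal days 1, 7 and 14 to follow how it changes early after birth. Each day had 3 libraries, with total counts between 50670191 and 62970768 per library. Libraries of the same day correlated with Pearson's r between 0.986 and 0.991 on log CPM across genes, against 0.885 to 0.891 between days 1 and 14. The first principal component took 68.3% of the variance and ordered the days by age, and the second took 16.2% and set day 7 apart from the other days. The pan-leukocyte gene Ptprc had at most 9 counts in any library. The basal keratins Krt5 and Krt14 were among the most abundant transcripts, at 21980.0 ± 911 and 12764 ± 318 CPM at day 1 (SD, n = 3).

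Transcripts that mark sex differed between the days. Xist, the RNA that coats the inactive X chromosome of females (mm10, chromosome X, 103460373 to 103483233), was at 1352 ± 428 CPM at day 1, at 0 counts in all day 7 libraries and at 2534 ± 184 CPM at day 14. The Y-linked gene Ddx3y (chromosome Y, 1260715 to 1286628) was at 41.8 ± 13.3 CPM at day 1, 105 ± 5.9 CPM at day 7 and 0 counts in all day 14 libraries. Day 1 libraries therefore held transcripts of both kinds, day 7 only the Y-linked ones and day 14 only Xist. This difference accompanies every comparison between the days. The day 7 libraries also have headers of another style. A separate preparation of them cannot be told apart from age in either step that involves day 7.

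**Figure D1:**
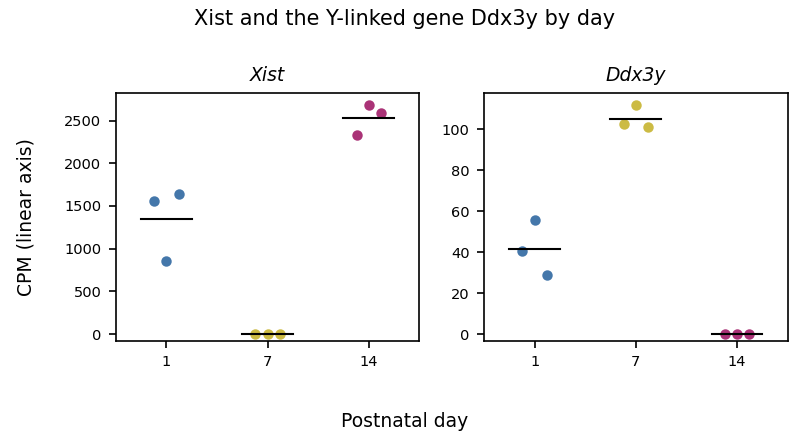
CPM (linear axis) of Xist and Ddx3y against postnatal day; points are the 3 libraries of each day and lines their means. Xist had 0 counts in all day 7 libraries and Ddx3y in all day 14 libraries.

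From day 1 to day 7, the lists of class I antigen presentation, Skint and barrier lipid genes passed camera upwards and those of imprinted growth and melanocyte genes downwards, and none of the 40 lists passed with an estimated correlation (smallest adjusted p = 0.053). H2-K1, a classical class I heavy chain (gene 14972, chromosome 17, 33996012 to 34000619), went from 21.2 ± 2.79 to 209.5 ± 21.2 CPM (log2 fold change 3.31 ± 0.12, adjusted p = 3.25e-08). Ptch1, a Hedgehog receptor that is itself induced by the pathway (chromosome 13, 63508328 to 63573460), fell from 538 ± 60.3 to 66.1 ± 2.56 CPM (log2 fold change -3.03 ± 0.08, adjusted p = 3.01e-10). Dct, an enzyme of melanin synthesis (chromosome 14, 118012790 to 118052246), fell from 199 ± 12.3 to 62.6 ± 4.84 CPM. Of 14507 genes tested with edgeR, 7171 changed, 3695 of them higher and 3476 lower at day 7 (3575 and 3686 with DESeq2, 3519 and 3625 with RLE size factors, 775 and 1013 against a fold of 1.5), and 691 rose and 1203 fell by more than 2-fold. With library totals alone as scaling, the median of all genes moved from -0.001 to -0.1 on the log2 scale, and 35.7% rather than 51.5% of the changed genes were higher at day 7. At day 7 the Y-linked genes were present and Xist was at 0. Immediate early and heat shock genes rose for 6 of 25 members and fell for 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.103). That list passed camera without day 1 library 6 (0.00454), day 7 library 2 (0.0312) or day 7 library 3 (0.0461), and with library totals alone (0.0463), against 0.484 at the highest over the alternatives.

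Among single genes with the largest rises were Slco2b1, an organic anion transporter (0.142 to 10.4 CPM), the beta-defensin Defb6 (0.292 to 10.1), the interleukin 12 receptor subunit Il12rb2 (0.347 to 11.5) and Bbox1, an enzyme of carnitine synthesis (3.02 to 75.3). The hemoglobin gene Hba-a1 was at 0 counts at day 1 and 12.6 ± 12.8 CPM at day 7, at least 268-fold higher (adjusted p = 0.0275), or at least 124-fold without day 7 library 3. That call was lost without any single day 1 or day 14 library or day 7 library 1 (adjusted p from 0.0501 to 0.0667), and the values over all alternatives ran from 1.05e-08 with DESeq2 to 0.412 with limma-voom. Hbb-b2, another hemoglobin gene, rose from 0.446 ± 0.402 to 13.5 ± 6.87 CPM. Of the 6 tested erythroid genes 4 rose, but the list did not pass camera (adjusted p = 0.277, and 0.56 with an estimated correlation). Besides Xist, the largest falls included those of Hmga2, a chromatin protein of fetal growth (16.2 to 0.0323 CPM), Cemip, a hyaluronan-binding protein (14.1 to 0.206), the transcription factor Foxi3 (12.8 to 0.273) and Prss35 (16.3 to 0.416).

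Gene lists were counted with adjusted p over all genes, and a count adjusted over the list alone is given wherever it differs. Of 40 lists, 16 passed camera from day 1 to day 7, 10 upwards and 6 downwards. Class I antigen presentation genes rose for 12 of 15 members (13 adjusted over the list alone, median log2 fold change 1.51, or 1.56 with members at 0 counts set at their bound, camera adjusted p = 4.01e-07, adjusted p = 0.397 with an estimated correlation). H2-D1 rose from 132 ± 10.8 to 376 ± 34.7 CPM and B2m, the class I light chain, from 41.2 ± 1.44 to 169 ± 24.4 CPM. All 11 Skint genes, a family of epidermal immunoglobulin-like membrane proteins, rose (camera adjusted p = 4.01e-07, adjusted p = 0.23 with an estimated correlation). Skint7 rose from 14.4 to 78 CPM and Skint1 from 19.8 to 68 CPM. Of 28 cytokine and chemokine genes 15 rose and 4 fell (camera adjusted p = 0.00411, adjusted p = 0.397 with an estimated correlation). The skin chemokine Ccl27a was among the rises (2.55 ± 0.11 log2), as were Il34 (1.14 ± 0.09) and the alarmin Il33 (2.32 ± 0.08).

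Other immune lists did not pass camera in this step, although some members changed. Class II genes rose for 3 of 7 members (camera adjusted p = 0.366), at low levels such as 2.82 CPM of Cd74 at day 7. Of 36 interferon response genes 13 rose and 5 fell (camera adjusted p = 0.386, with a median of -0.07 and a mean of -0.014 although the test pointed upwards), with Usp18 at 2.25 ± 0.12 log2 and Parp14 at 1.24 ± 0.08. Of 11 antimicrobial and alarmin genes 4 rose and 2 fell, including a rise of the peptidoglycan-binding protein Pglyrp4 (2.24 ± 0.08 log2) and of the beta-defensin Defb1 (2.43 ± 0.12). The summed share of the whole list did not rise, at 0.0597 ± 0.0032% of counts at day 1 and 0.0557 ± 0.007% at day 7. Among 11 immune ligand genes 4 rose and 2 fell, and Vsir, a checkpoint protein, rose from 1.85 ± 0.39 to 21.5 ± 1.88 CPM.

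**Figure D2:**
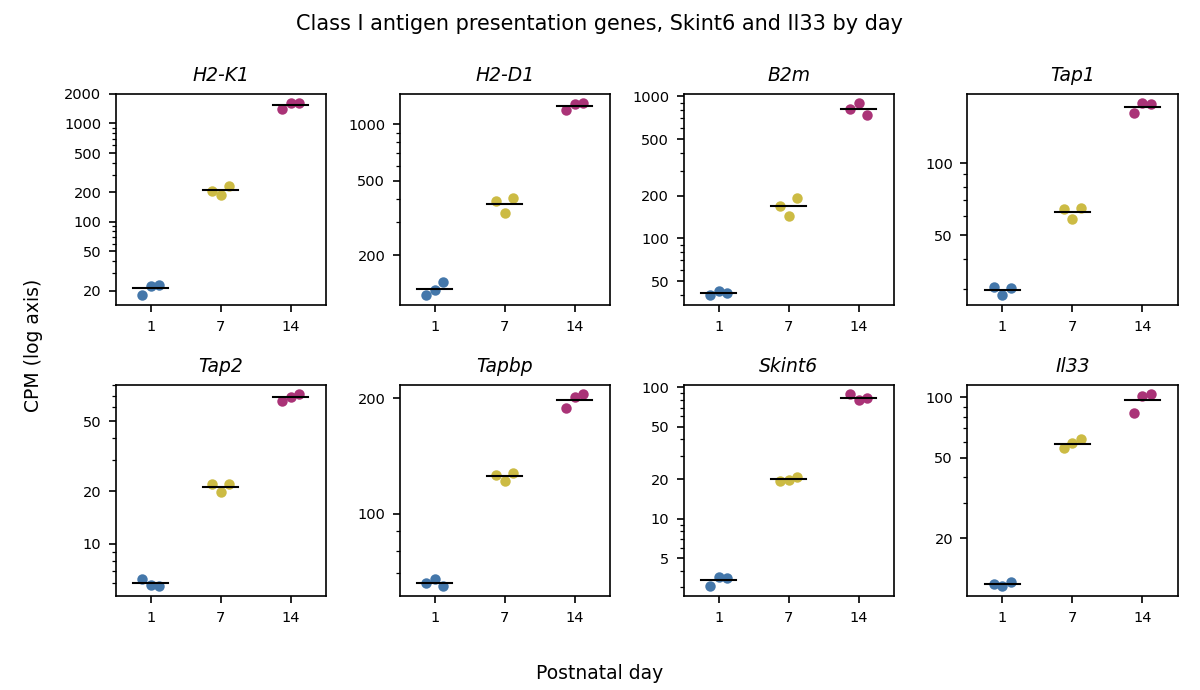
CPM (log axis) of H2-K1, H2-D1, B2m, Tap1, Tap2, Tapbp, Skint6 and Il33 against postnatal day; points are the 3 libraries of each day and lines their means. Each gene was lowest at day 1 and highest at day 14, with H2-K1 at a mean of 21.2, 209.5 and 1542 CPM.

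Of 15 spinous layer genes 10 rose and 0 fell from day 1 to day 7 (camera adjusted p = 0.000469, adjusted p = 0.439 with an estimated correlation). Ly6d rose, and the adhesion protein Dsg1a went from 626 ± 57.9 to 899 ± 10.7 CPM. Of 19 granular layer genes 11 rose and 2 fell (3 fell adjusted over the list alone, camera adjusted p = 0.00329, adjusted p = 0.439 with an estimated correlation). The transglutaminase Tgm3 rose from 131 ± 26.3 to 670.1 ± 18.3 CPM, while the protease Asprv1 fell from 198 ± 44.1 to 89.2 ± 23 CPM. Barrier lipid genes rose for 17 of 24 members and fell for 1 (18 and 1 adjusted over the list alone, camera adjusted p = 1.04e-05, adjusted p = 0.23 with an estimated correlation). The ceramide desaturase Degs1 and the elongase Elovl1 (0.50 ± 0.05 log2) were among the rises. Cornified envelope genes rose for 6 of 13 members (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.397 with an estimated correlation), but the call was lost without day 1 library 4 (0.0646) or day 1 library 5 (0.0509). Over the alternatives the adjusted p ran from 0.00119 with library totals alone to 0.0849 without a low-count filter. The suprabasal keratins Krt1 and Krt10 did not pass the test (adjusted p = 0.712 and 0.901); without day 1 library 4 both did, at log2 fold changes of -0.225 and -0.214 (adjusted p = 0.00116 and 0.0164, against up to 0.919 and 0.992 under the other alternatives).

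Imprinted growth genes fell for 13 of 16 members and rose for 1 (14 and 2 adjusted over the list alone, camera adjusted p = 7.27e-05, adjusted p = 0.23 with an estimated correlation). H19, a noncoding RNA of the Igf2 locus (chromosome 7, 142575530 to 142578146), fell from 7306 ± 1091 to 2427 ± 290.5 CPM. The growth factor Igf2 (chromosome 7, 142650768 to 142666816) fell from 613 ± 198 to 78.5 ± 34.5 CPM and Peg3 from 326 ± 28 to 118 ± 4.3 CPM. Ribosomal protein genes rose for 75 of 81 members and fell for 1 (camera adjusted p = 1.11e-15, adjusted p = 0.439 with an estimated correlation), by a median of 0.329 on the log2 scale. Of 78 oxidative phosphorylation genes 45 rose and 3 fell (53 and 3 adjusted over the list alone, camera adjusted p = 9.14e-07, adjusted p = 0.511 with an estimated correlation). Proliferation genes fell for 15 of 38 members and rose for 2 (13 and 2 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.56 with an estimated correlation). That call was lost without day 1 library 5 (0.104), day 7 library 1 (0.0798) or day 7 library 3 (0.061), with values from 0.00693 to 0.104 over the alternatives. Mki67 was at 437 ± 21.1 and 449 ± 13.9 CPM and did not pass the test.

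Hair matrix regulators fell for 10 of 17 members and rose for 5 (camera adjusted p = 0.0258, adjusted p = 0.439 with an estimated correlation, from 0.016 to 0.092 over the alternatives, the highest with library totals alone). Ptch1 was among the falls and the ligand Wnt3 among the rises (0.87 ± 0.05 log2). Glycolysis and hypoxia genes rose for 12 of 25 members and fell for 2 (camera adjusted p = 0.0263, adjusted p = 0.56 with an estimated correlation), a call lost without day 1 library 4 (0.0793) or day 7 library 1 (0.0867, the highest over the alternatives, against a lowest of 0.00454). Aldoa rose by 0.45 ± 0.05 on the log2 scale. Replication histone genes fell for 12 of 62 members and rose for 1 (4 fell and 0 rose adjusted over the list alone, camera adjusted p = 0.0277, adjusted p = 0.644 with an estimated correlation). That call was lost without day 1 library 5 (0.1), day 1 library 6 (0.0674) or day 7 library 1 (0.0881), and with library totals alone (0.154), against 0.00131 at the lowest.

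All 13 melanocyte genes fell from day 1 to day 7 (median log2 fold change -1.88, camera adjusted p = 5.98e-09, adjusted p = 0.053 with an estimated correlation). Pmel fell from 97.4 ± 4.37 to 26.5 ± 4.28 CPM and Trpm1 from 50.3 ± 3.53 to 11.3 ± 0.29 CPM. Fibroblast matrix genes fell for 8 of 17 members and rose for 1 (camera adjusted p = 0.00577, adjusted p = 0.56 with an estimated correlation). The fibronectin gene Fn1 fell from 277 ± 18.4 to 163 ± 12.3 CPM and Dcn from 107 ± 26.9 to 11.5 ± 3.24 CPM. The collagen gene Col1a1 varied between libraries of a day (7.61 ± 7.61 and 4.35 ± 5.67 CPM) and did not pass the test.

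From day 7 to day 14, the lists of class I, class II and Skint genes passed camera upwards and those of proliferation and melanocyte genes downwards, and none of the 40 lists passed with an estimated correlation (smallest adjusted p = 0.236). H2-K1 rose from 209.5 ± 21.2 to 1542 ± 109.9 CPM (log2 fold change 2.88 ± 0.11, adjusted p = 2.79e-08). Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716450), fell from 449 ± 13.9 to 243 ± 8.05 CPM (log2 fold change -0.88 ± 0.05, adjusted p = 1.4e-08). Krt77, a type II keratin (chromosome 15, 101858731 to 101869706), rose from 1010.2 ± 65.6 to 2843 ± 308 CPM (log2 fold change 1.49 ± 0.19, adjusted p = 0.000285). In total 9808 genes changed, 4713 higher and 5095 lower at day 14 (4969 and 4777 with DESeq2, 4941 and 4748 with RLE size factors, 1907 and 1286 against a fold of 1.5), of which 1604 rose and 1124 fell by more than 2-fold. With library totals alone the median of all genes moved from -0.035 to -0.21 and 34.9% rather than 48.1% of the changed genes were higher at day 14. Xist was at least 49300-fold higher and Ddx3y at least 1790-fold lower at day 14, so sex-linked transcripts and age changed together in this step. Immediate early and heat shock genes, which respond to tissue handling, rose for 17 of 25 members and fell for 4 (camera adjusted p = 0.0508, adjusted p = 0.835 with an estimated correlation). That list passed camera without day 1 library 5 (0.0322) or 6 (0.0428), day 7 library 1 (0.00279) or 3 (0.0444), or day 14 library 5 (0.0483). It also passed with library totals alone (0.00873), without a low-count filter (0.0285) and without the 50 most abundant genes in the scaling (0.0468), and with fry in place of camera (0.0375), against 0.0783 at the highest with camera at its fixed correlation.

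Among other genes with the largest rises, Ache, the acetylcholinesterase gene (chromosome 5, 137288247 to 137294466), went from 1.53 ± 0.121 to 75.7 ± 1.92 CPM. H2-Q6 had 0 counts at days 1 and 7 and was at least 585-fold higher at day 14, while H2-Q9 went from 0.116 ± 0.201 to 38.7 ± 3.64 CPM and Skint5 from 0.457 ± 0.163 to 20.3 ± 1.12 CPM. Kctd12 had 0 counts at day 7 and was at least 688-fold higher at day 14 (adjusted p = 0.0454), a call lost without any single day 7 or day 14 library (adjusted p from 0.0774 to 0.101) or without a low-count filter (0.0556, against 2.03e-09 at the lowest over the alternatives). At day 1 Kctd12 was at 12 CPM in library 4 and at 0 in libraries 5 and 6. A value of 0 for this gene can therefore also arise between libraries of a day. The largest falls included Eif2s3y on the Y chromosome (at least 974-fold lower), the aldehyde oxidase Aox4 (29 to 0.197 CPM), the stefin A family protease inhibitor Stfa3 (1801 to 28.4 CPM) and Fras1, an extracellular protein of the epidermal basement membrane (chromosome 5, 96373777 to 96784733; 168 to 2.9 CPM). Hba-a1 went from 12.6 to 0.0133 CPM (adjusted p = 0.0238), a call lost without day 7 library 1 (0.0564) or any single day 14 library (0.0851 to 0.0884), with values from 6.95e-07 to 0.444 over the alternatives.

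Immune lists accounted for several of the 11 lists past camera, 6 upwards and 5 downwards. Class I genes rose for 14 of 15 members (median log2 fold change 1.74, also with members at their bound, camera adjusted p = 7.4e-08, adjusted p = 0.413 with an estimated correlation). The peptide transporter genes Tap1 (62.8 ± 3.74 to 172 ± 8.91 CPM) and Tap2 (21.2 ± 1.36 to 68.3 ± 3.08 CPM) were among them. Class II genes rose for 6 of 7 members (camera adjusted p = 0.00352, adjusted p = 0.281 with an estimated correlation). Cd74 reached 14.2 ± 0.179 CPM and H2-Aa 11.5 ± 0.576 CPM. The leukocyte gene Cd207 had 9 to 13 counts per library at day 7 and 34 to 64 at day 14. Tyrobp, another, had 5 to 14 and 40 to 81. Whether leukocytes carried the class II rise was not tested. Skint genes rose for 10 of 11 members (camera adjusted p = 0.000201, adjusted p = 0.389 with an estimated correlation). Skint7 rose to 202 ± 17.8 CPM and Skint6 by 2.06 ± 0.07 on the log2 scale. Of 10 tested leukocyte genes 8 rose (9 adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.372 with an estimated correlation). Cd68 reached 8.73 ± 1.01 CPM and Coro1a 1.64 ± 0.335 CPM. Of 36 interferon response genes 13 rose and 5 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.117, but 0.0222 with library totals alone and up to 0.238 over the alternatives), and of 28 cytokine and chemokine genes 12 rose and 7 fell (camera adjusted p = 0.41), with rises of Cxcl16 (1.02 ± 0.06 log2) and Cx3cl1 (0.91 ± 0.06). In the antimicrobial and alarmin list 3 rose and 5 fell of 11, and in the immune ligand list 7 rose and 3 fell of 11, with Nectin2, an adhesion ligand, at 1.56 ± 0.07 log2.

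Proliferation genes fell for 36 of 38 members (median log2 fold change -0.985, camera adjusted p = 1.01e-13, adjusted p = 0.329 with an estimated correlation). The topoisomerase Top2a fell from 337 ± 25.3 to 167 ± 8.42 CPM. Replication histone genes fell for 50 of 62 members (camera adjusted p = 2.59e-06, adjusted p = 0.65 with an estimated correlation). The linker histone Hist1h1c fell from 51.2 ± 4.88 to 35.1 ± 3.31 CPM. Ribosomal protein genes fell for 74 of 81 members and rose for 1 (median -0.257, camera adjusted p = 9.44e-10, adjusted p = 0.749 with an estimated correlation). Rplp0 fell from 2919 ± 87.5 to 2409 ± 139 CPM. Oxidative phosphorylation genes fell for 68 of 78 members and rose for 1 (70 and 1 adjusted over the list alone, camera adjusted p = 8.78e-12, adjusted p = 0.556 with an estimated correlation). The ATP synthase subunit Atp5b fell from 1294 ± 36.5 to 925 ± 7.16 CPM. Imprinted growth genes fell for 10 of 16 members and rose for 1 (camera adjusted p = 0.0513, and 0.0483 without day 7 library 2, 0.0333 without day 7 library 3 or 0.0387 with RLE size factors). Over the alternatives that value ran from 0.0267 without a low-count filter to 0.219 with library totals alone.

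Spinous layer genes rose for 11 of 15 members and fell for 1 (camera adjusted p = 0.00184, adjusted p = 0.65 with an estimated correlation). The fall was that of Krt1, the main keratin of this layer, from 6324 ± 242 to 3369.8 ± 44.8 CPM, while Krt77 and Dsg1a rose. Barrier lipid genes rose for 17 of 24 members and fell for 2 (camera adjusted p = 0.000907, adjusted p = 0.332 with an estimated correlation). Elovl4, which makes the ultra-long fatty acids of skin ceramides, rose (71.7 ± 2.07 to 179 ± 20.2 CPM), as did Abhd5, a lipase activator (83.5 ± 1.35 to 147 ± 8.29 CPM). The basal keratins Krt5 and Krt14 fell, with log2 fold changes of -0.53 ± 0.05 and -0.57 ± 0.05. Melanocyte genes fell for 12 of 13 members (camera adjusted p = 0.000476, adjusted p = 0.236 with an estimated correlation). Dct fell to 3.88 ± 1.57 and Pmel to 1.42 ± 0.448 CPM, while the transcription factor Mitf rose from 6.01 ± 1.52 to 10.3 ± 0.772 CPM.

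**Figure D3:**
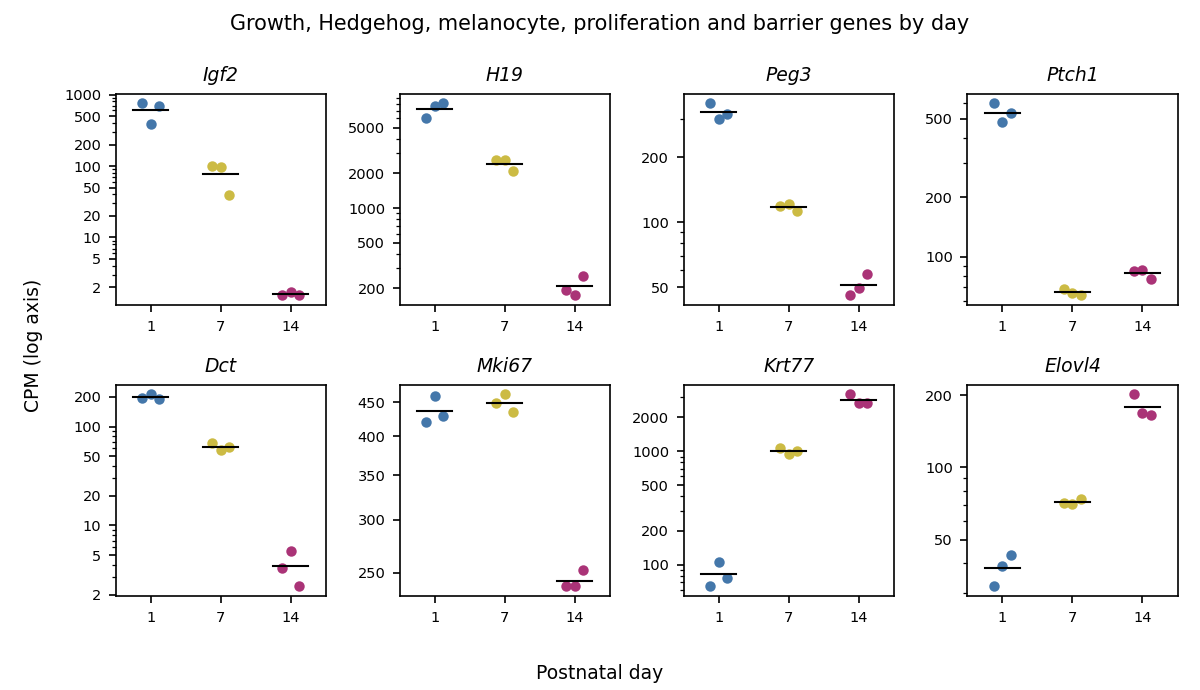
CPM (log axis) of Igf2, H19, Peg3, Ptch1, Dct, Mki67, Krt77 and Elovl4 against postnatal day; points are the 3 libraries of each day and lines their means. Igf2 went from a mean of 613 to 1.61 CPM and Krt77 from 82.3 to 2843 CPM between days 1 and 14.

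Over the whole interval from day 1 to day 14, the lists of class I, Skint and barrier lipid genes passed camera upwards and those of imprinted growth, proliferation and melanocyte genes downwards, and none of the 40 lists passed with an estimated correlation (smallest adjusted p = 0.197). H2-K1 rose by 6.19 ± 0.13 on the log2 scale (adjusted p = 1.93e-10) and B2m (chromosome 2, 122147687 to 122153082) by 4.31 ± 0.12 (adjusted p = 6.22e-10). Igf2 fell from 613 ± 198 to 1.61 ± 0.0928 CPM (log2 fold change -8.57 ± 0.60, adjusted p = 1.61e-05). Krt77 rose by 5.11 ± 0.22 (adjusted p = 4.46e-07). Of the genes tested 10716 changed, 5150 higher and 5566 lower at day 14 (2619 and 2435 against a fold of 1.5), and 2118 rose and 2080 fell by more than 2-fold. With library totals alone the median of all genes moved from -0.046 to -0.319 and 31.9% rather than 48.1% of the changed genes were higher at day 14. Y-linked genes were present at day 1 and at 0 at day 14.

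The largest rises over the interval were those of H2-Q9, H2-Q6, Skint5 and the neuropeptide gene Calcb, which had 0 counts at day 1 and were at least 820-fold, 638-fold, 430-fold and 380-fold higher at day 14. They were followed by Il20ra, a receptor subunit for cytokines of the interleukin 20 family (0.347 ± 0.0977 to 87.4 ± 7.24 CPM), and the bicarbonate transporter Slc4a8 (0.318 ± 0.137 to 68.2 ± 8.62 CPM). Besides Y-linked genes, the largest falls were those of Hmga2 (16.2 to 0.0258 CPM), Igf2, Mpped1 (15.2 to 0.0399 CPM) and the adhesion molecule Ncam1 (21.6 to 0.0849 CPM).

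Of the 40 lists 17 passed camera over this interval, 11 upwards and 6 downwards. All 15 class I genes rose (median log2 fold change 3.52, also with members at their bound, camera adjusted p = 1.61e-07, adjusted p = 0.339 with an estimated correlation), as did all 11 Skint genes (camera adjusted p = 1.84e-05, adjusted p = 0.243 with an estimated correlation) and 6 of 7 class II genes (camera adjusted p = 0.0107, adjusted p = 0.243 with an estimated correlation). Of 28 cytokine and chemokine genes 15 rose and 6 fell (camera adjusted p = 0.0145, adjusted p = 0.339 with an estimated correlation). The abundant chemokine Cxcl14 fell from 667 ± 34.9 to 543 ± 29.3 CPM, while Ccl27a and Il34 rose by 2.29 ± 0.11 and 1.42 ± 0.09 on the log2 scale. Of 10 leukocyte genes 9 rose (camera adjusted p = 0.0361, adjusted p = 0.339 with an estimated correlation, 0.051 without day 1 library 4 and 0.00339 at the lowest over the alternatives). Interferon response genes rose for 17 of 36 members and fell for 6 (16 and 5 adjusted over the list alone, camera adjusted p = 0.0644). That list passed camera without day 7 library 2 (0.0455), day 7 library 3 (0.0498) or day 14 library 6 (0.0416), with library totals alone (0.00732) and with the replicate block by header number (0.0425), against 0.121 at the highest. In the antimicrobial and alarmin list 5 rose and 4 fell of 11, and in the immune ligand list 6 rose and 4 fell of 11.

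Barrier lipid genes rose for 21 of 24 members and 0 fell (camera adjusted p = 5.95e-06, adjusted p = 0.197 with an estimated correlation), Elovl4 by 2.23 ± 0.12 on the log2 scale. Spinous layer genes rose for 13 of 15 members and fell for 1 (camera adjusted p = 0.000149, adjusted p = 0.422 with an estimated correlation). Granular layer genes rose for 16 of 19 members and fell for 2 (camera adjusted p = 0.00166, adjusted p = 0.358 with an estimated correlation). The calmodulin-like Calm4 went from 195 ± 8.43 to 451 ± 42 CPM. Retinoid metabolism genes rose for 9 of 13 members and fell for 2 (camera adjusted p = 0.0361, adjusted p = 0.243 with an estimated correlation). The receptor Rarg and the retinaldehyde reductase Dhrs3 were among the rises. Glycolysis and hypoxia genes rose for 18 of 25 members and fell for 1 (camera adjusted p = 0.00634, adjusted p = 0.693 with an estimated correlation).

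Proliferation genes fell for 36 of 38 members and rose for 1 (camera adjusted p = 1.64e-11, adjusted p = 0.243 with an estimated correlation). The rise was that of the replication clamp gene Pcna (log2 fold change 0.14 ± 0.06, adjusted p = 0.0463). It was lost without day 1 library 5 (0.104) or 6 (0.196), day 7 library 2 (0.073) or 3 (0.0643), or day 14 library 4 (0.156) or 6 (0.148), and at its lowest over the alternatives the value was 0.0201. It was also lost without the 50 most abundant genes in the scaling (0.0587), without a low-count filter (0.0749), on autosomal genes only (0.0575), with the replicate block by header number (0.0656) and against a fold of 1.5, and it changed sign with library totals alone. Replication histone genes fell for 52 of 62 (camera adjusted p = 3.2e-06, adjusted p = 0.467 with an estimated correlation) and imprinted growth genes for 13 of 16 (camera adjusted p = 0.000822, adjusted p = 0.243 with an estimated correlation). H19 fell from 7306 ± 1091 to 209 ± 44.1 CPM. Oxidative phosphorylation genes fell for 48 of 78 members and rose for 4 (camera adjusted p = 0.000931, adjusted p = 0.796 with an estimated correlation). All 13 melanocyte genes fell (camera adjusted p = 2.32e-05, adjusted p = 0.197 with an estimated correlation). Fibroblast matrix genes fell for 9 of 17 members and rose for 1 (camera adjusted p = 0.0276, adjusted p = 0.796 with an estimated correlation). Fn1 fell, and Sparc went from 182 ± 8.76 to 50.4 ± 5.24 CPM. The call for the list was lost without day 1 library 4 (0.0705) and with library totals alone (0.189, against 0.00236 at the lowest over the alternatives). Immediate early and heat shock genes rose for 15 of 25 members and fell for 3 (camera adjusted p = 0.0107, adjusted p = 0.796 with an estimated correlation). Fos rose from 3467 ± 336 to 6684 ± 401 CPM and Fosb from 1229 ± 117 to 8478 ± 926 CPM.

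Over all 3 days, 11904 of the 14507 genes varied (edgeR quasi-likelihood F test). Genes that rose in both steps numbered 1784, against 1200 for independent steps, and 1480 fell in both against 1221. A turn at day 7 was found for 1954 genes, of which 1050 were highest and 904 lowest at day 7. More were lowest than highest with DESeq2 (909 highest, 1036 lowest), RLE size factors (911, 1007), library totals alone (894, 899) and a filter of 1 CPM in 3 libraries (932, 944). Independent steps would give 1298 and 1129. Simulations of unchanged groups gave at most 1, but at most 3 genes were called there for a pair of days. That value is therefore no measure of the turns that arise when many genes change. The steps share the day 7 libraries, which are too few to split, and this sharing can raise the number of turns. The observed numbers of turns lay below those of independent steps. High at day 7 were Tgm3 (131, 670.1 and 115 CPM at days 1, 7 and 14), Pdzrn4 (4.35, 24.8 and 7.76), Serpina3b (18, 54.9 and 11.5) and the hemoglobin gene Hbb-b1 (1.08, 30.8 and 1.93). Low at day 7, besides Xist, were Hpgds, a prostaglandin D synthase (51, 13 and 118 CPM) and Erdr1 (260.1, 80.3 and 445). Cemip was also low at day 7, but its second step lost the call without day 7 library 2 (adjusted p = 0.0627, against 0.00157 at the lowest). Among lists, ribosomal protein genes rose and then fell. Between days 1 and 14, 25 of 81 rose and 6 fell (18 and 3 adjusted over the list alone, camera adjusted p = 0.297, but 0.0173 without day 14 library 6 and from 0.0141 to 0.804 over the alternatives), and their median changed sign from 0.083 to -0.19 with library totals alone.

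The summed share of all counts differed between days for 37 of 40 lists (exact permutation test, Benjamini-Hochberg adjusted p under the threshold). Spinous layer genes (adjusted p = 0.571), glycolysis and hypoxia genes (0.311) and follicle stem and outer sheath genes (0.0564) did not pass. Class I genes took 0.0424 ± 0.0019% of counts at day 1, 0.114 ± 0.01% at day 7 and 0.433 ± 0.025% at day 14 (SD, n = 3; exact permutation p = 0.00357, the smallest possible). Imprinted growth genes took 0.963 ± 0.1%, 0.33 ± 0.035% and 0.0419 ± 0.0046%, and melanocyte genes 0.0541 ± 0.0018%, 0.0147 ± 0.0011% and 0.00205 ± 0.00014%. Leukocyte genes took 0.000749% of counts at day 1 and 0.00168% at day 14. Erythroid genes took 0.000295%, 0.00731% and 0.000643% at days 1, 7 and 14. Antimicrobial and alarmin genes took 0.0597%, 0.0557% and 0.0408% (exact permutation test, adjusted p = 0.0168). Immediate early and heat shock genes took 2.99 ± 0.35%, 3.37 ± 0.37% and 4.6 ± 0.15%.

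**Figure D4:**
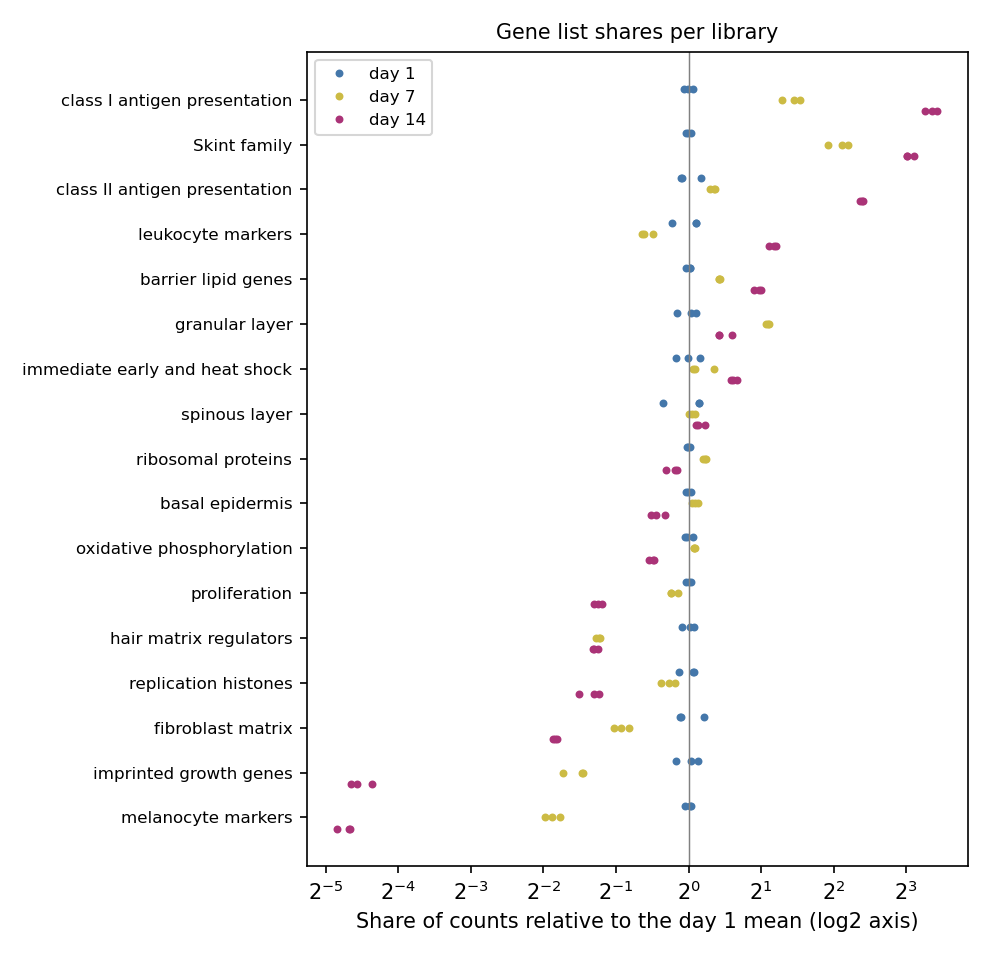
Share of all counts taken by 17 gene lists in each library, relative to the mean of day 1 (log2 axis); points are single libraries, coloured by day. Class I genes stood at 10.2 times and melanocyte genes at 0.0378 times their day 1 mean at day 14.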

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

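Results were recomputed under the alternatives listed for them, and not each was run for each. Lists were not run with DESeq2, limma-voom, the filter of 1 CPM, the compared days only, a fold of 1.5, the stricter threshold or autosomal genes only. List shares were run only without the 50 most abundant genes and without each library, and the counts over all days and of turns were not run against a fold of 1.5 or on the compared days only. The fits on autosomal genes only and with a replicate block by header number were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of those reported under DESeq2, limma-voom, other scalings and filters, an adjusted p under 0.01 and autosomal genes only (6932, 9532 and 10387 for the 3 pairs of days, 11542 over all days and 1883 turns), except that the turn count was 1150 at an adjusted p under 0.01. Testing against a fold of 1.5, which asks for larger changes by construction, left 1788 genes for day 7 versus day 1, 3193 for day 14 versus day 7 and 5054 for day 14 versus day 1. Without each library in turn, the counts ranged from 6096 to 7268, 9114 to 9897 and 10250 to 10784, those over all days from 11530 to 11720 and the turns from 1475 to 1911. Lists past camera then ranged from 13 to 17, 11 to 13 and 15 to 19, and list shares from 37 to 38. With an estimated inter-gene correlation 0, 0 and 0 lists passed, and with fry, which does not compare a list with other genes, 31, 30 and 33. Fold changes of 2 named genes reversed for day 14 versus day 1 with library totals alone: Pcna to -0.129 (adjusted p = 0.0565) and Pkm to -0.13 (adjusted p = 0.0303). That scaling moved the median of all genes from -0.046 to -0.319, a downward shift that these 2 genes shared. Among the other values of named genes, 5086 kept direction and side of the threshold, 151 lost and 6 gained the call. Among those of lists, 1692 kept the side of the threshold, 61 lost and 87 gained the call. The sign of the median was not kept by every list. That of basal epidermis genes went from 0.169 to -0.105 for day 14 versus day 1 with library totals alone. No paired analysis was possible by title number because the column headers carry other numbers. The replicate block by header number at days 1 and 14 gave 10170 genes and 19 lists for day 14 versus day 1; same-numbered libraries deviated together with r of 0.014, 0.01 and 0.104, so these numbers were not taken as pairs. The planned limma-trend fits on TPM and FPKM and the list shares from TPM were not run. Those headers give the day but not the sample, which comparisons by day would not have needed. At total counts of 50670191 to 62970768 per library, 28% to 43% of the smallest simulated changes were recovered. Few genes were changed in that simulation, all with a mean of at least 1 CPM, so these shares do not give the recovery in the data.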

Other observations

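The genes of the first paragraphs and all tests given here were chosen after the results were seen, except the test of length and GC content over all turned genes. Of the genes with an adjusted p in these paragraphs, Gli1 and Lef1 belong to the hair matrix list and the others to no list, and the alternatives were not run for them singly, so each value stands for that gene alone (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p). Igf2bp1, an RNA-binding protein of fetal tissues, fell from 34 ± 4.86 to 6.31 ± 0.445 and 0.255 ± 0.145 CPM at days 1, 7 and 14 (SD, n = 3; adjusted p = 4.56e-07 and 4.68e-08 for the steps). The proteoglycan gene Gpc3 fell from 119.6 to 44.4 and 12.4 CPM (adjusted p = 1.82e-07 and 1.74e-08). Frem2, an extracellular protein of the epidermal basement membrane, fell from 489 CPM at day 1 to 153 at day 14 (adjusted p = 2.82e-10). Gli1, a target of the Hedgehog pathway, fell from 149.7 ± 11.1 to 7.95 ± 0.534 CPM between days 1 and 7 (log2 fold change -4.23 ± 0.15, adjusted p = 7.86e-08). Edar, a receptor of hair placodes, fell from 50.7 to 3.25 CPM (adjusted p = 1.66e-05) and the transcription factor Lef1 from 74.3 to 3.95 CPM (adjusted p = 0.000568).

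Nr1d1, a repressor of the circadian clock, rose from 9.08 ± 0.681 to 40.7 ± 1.2 and 353 ± 24.5 CPM (log2 fold change from day 1 to day 14 5.28 ± 0.07, adjusted p = 1.9e-13). Arntl, a clock activator, rose from 21.7 CPM at day 1 to 90.7 at day 14 (adjusted p = 5.61e-11), and the hour of sampling is not given in the sources used here. Tsc22d3, which responds to glucocorticoids, rose from 9.19 ± 1.91 to 129 ± 3.15 CPM (adjusted p = 3.84e-08), while Fkbp5, another gene known to respond to them, fell from 20.6 to 5.12 CPM (adjusted p = 2.99e-08). Stfa1, a close copy of Stfa3, fell from 167 CPM at day 7 to 5.17 at day 14 (adjusted p = 1.76e-10). The interferon gamma receptor subunit Ifngr1 rose from 37.5 ± 5.22 to 120.2 ± 7.81 and 247 ± 22.5 CPM (adjusted p = 9.52e-07 and 1.11e-05 for the steps). In all, 12 genes had 0 counts in every library of a day and a mean of at least 10 CPM in another. Among them were Kctd12 (also at 0 in day 1 libraries 5 and 6), H2-Q6 and Calcb.

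In splits of the 6 libraries of a pair of days, the real split gave 7171, 9808 and 10716 changed genes and the highest of the other splits 1, 2 and 0 (1 of 10 splits as large each time). For lists past camera the real splits gave 16, 11 and 17 and the highest others 20, 19 and 17, with 3, 9 and 3 of 10 splits as large. With 10 splits a share under 0.05 is not possible in these comparisons. For lists this is not the only limit, because mixed splits passed as many lists or more in each comparison. The number of lists past camera therefore does not tell the real days from mixed groups. Of 100 drawn from 280 splits of all 9 libraries, only the real one reached 11904 genes varying over the days (highest other 7067). Chance is argued against for that count only as an arrangement of these libraries. The libraries of a day may be pools or technical copies, so chance differences between animals cannot be excluded. A turn depends on which group stands in the middle, which makes 840 splits. Of 100 drawn from these, only the real one reached 1954 turned genes (highest other 2). That draw held no other split with a whole day in the middle, and all 29 of these were therefore run. As many turned genes or more were found in 20 of them, up to 8043, each with the day 1 or the day 14 libraries as the middle group, which points to the structure of the samples. The real split and these make up 2.5% of all 840, if no other kind of split reaches the real count. That condition was not checked for the splits not drawn. With all days kept whole, the count was 5291 with day 1 in the middle, 8043 with day 14 and 1954 with day 7. The count therefore shows that libraries group by day, and it cannot exclude chance for a turn at day 7. Both runs replaced, after its values were seen, a draw that left out the other arrangements of the real groups.

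Class I antigen presentation genes rose with age. Leukocytes that escaped the CD45.2 gate are argued against, since the rise of the summed leukocyte markers was 0.238% of that of the class I genes. A difference of sex alone is argued against for 12 of the 15 members, which were lower at day 1, where both sexes' transcripts were present, than at both other days; it stays open for the other members. Reads moved between copies of the H2 genes are argued against as the whole cause, because 8 of 8 members outside the H2 genes rose and the summed share of the H2 genes was 11.8 times higher at day 14. Age itself may account for the rise and was not tested apart from these.

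At day 7, 1954 genes turned. A difference of sex alone is argued against for 341 turned genes whose day 1 lay beyond day 14 (466 with library totals alone), but for the other 1613 sex and age cannot be told apart, because day 7 libraries held only Y-linked transcripts and day 14 libraries only Xist. A separate preparation of the day 7 libraries also stays open, since the 3 libraries whose headers have another style are exactly those of day 7. That limit holds for all changes in both steps, not only for turns. Transcript length and GC content removed 12.1% of the gap between genes high and low at day 7 (95% bounds 9.52 to 15.6). This was below the share set beforehand for a main cause. The genes were picked by the same departure, however, which favours a remaining gap, and the bounds resample genes, not libraries. The value shows only that a smooth trend carried a small part of the gap among genes picked this way. For the ribosomal protein and oxidative phosphorylation lists, length and GC content removed 48.3% and 51.3% of the departure at day 7, a large part. The bound for a whole cause, 100% removed, replaced a stricter one after these values were seen. A smooth trend of the other genes may also correct these lists too little. The remainder therefore does not decide whether length and GC content were the whole cause.

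Melanocyte markers fell, and fewer melanocytes among the sorted cells is a candidate explanation in line with 12 of 13 markers falling at day 7 and by more than 4-fold by day 14. A difference of sex alone is argued against, because 13 of 13 markers were higher at day 1 than at both other days. A larger share of keratinocytes as the whole cause would lower all other cell types alike, if keratinocytes made none of their markers. The test of this replaced earlier ones after their values were seen. The melanocyte list was taken up because it fell, which favours a low rank for it. Over the pairs of libraries, the share at day 14 relative to day 1 was at most 0.0411 for melanocytes and higher in 10 of 10 other lists. Of these the leukocyte list rose to 2.24 times (9 members rose and 0 fell of 10), the adipocyte list to 2.06 (2 rose and 2 fell of 5) and the Schwann cell list to 1.62 (5 rose and 6 fell of 14), while 5 lists fell to between 0.236 and 0.641 times; of all 101 tested members 26 rose and 35 fell, 27 by more than 4-fold, and those that keratinocytes also make would fall less. The lists did not share 1 factor, but this does not decide whether a larger share of keratinocytes was the whole cause. A larger share of keratinocytes as part of the fall, lower expression within melanocytes, and age as such stay open and were not tested.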
